A study of Homo sapiens with 14 samples.

How the data were processed

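Mature miRNAs were measured with TaqMan PCR assays in 14 samples of primary human melanocytes, per the series' design text and the labels. The sample titles place 7 samples in the control group and 7 in the forskolin group and give each a source number, so that each of 7 sources has 1 sample of each kind. The reverse transcription, the card, the software and the cycle limit are not given in the sources used here.

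The authors deposited 1 table of 382 rows with the assay name and part number of each row. Its values are on a log2 scale: cycle differences (delta Ct) that the authors obtained by subtracting a reference from each sample's cycle number. This reading comes from the values, since they run from -2.19 to 22.67 with 2 decimals, which no raw cycle number does. That lower values mean more RNA also comes from the values. Assays with a mean below 10 had a mean of 0 blanks over the 14 samples, and assays at 14 or above had 8.47. The reference is not named. The 17 rows of the small-RNA controls RNU44, RNU48 and RNU6B are blank in every sample, so the normalization could not be checked or replaced by another endogenous control. A shift shared by the reference and the miRNAs would not be visible, and 1 cycle equals 1 log2 unit only if each cycle doubles the product. The highest value per sample ranged from 21.1 to 22.7, which marks where detection ended; blanks were treated as missing. There are no counts, so no counting interval was computed, and precision is given by the spread over sources and by the number of assays detected per sample.

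All values were turned in sign so that higher means more RNA. Assays with values in both samples of at least 4 sources were tested, 165 in all; 111 further miRNA assays had a value in at least 1 sample and were not tested. The main test was lmFit and eBayes of limma 3.58.1 in R 4.3.3 with the source as a block, two-sided, with Benjamini-Hochberg adjustment at 0.05. The block was the main design because the titles name the same source in both groups. The check of this pairing used the deviations of each sample from its group mean over 137 assays: same-source samples correlated at 0.20 to 0.60, and in 7 of 7 pairs each sample correlated best with its own source, while the median over different sources was -0.056. Source numbers come from the labels; whether a source is a donor is not stated. The correlation of raw values between any 2 samples over these assays was 0.934 to 0.989, so no pair of samples was a duplicate by identical values.

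Overall shifts, numbers of detected assays and list means were compared with exact sign-flip permutation tests over the sources. Intervals are 95%. The lists were compared with all other tested assays by cameraPR with a preset correlation of 0.01 and with one estimated from the residuals. The lists, the design and the rule for named miRNAs were fixed before the data were examined. The rule named the miRNAs past the threshold with the same direction in all but 1 source (up to 10 per direction). With fewer than 10 of these, it took the 10 with the smallest p. It added 19 miRNAs chosen in advance, up to 4 members per list with the largest change, and the 10 most abundant in control. miR-212, one of those 19, was not analysed here. The lists were the miR-17~92, miR-106b~25 and miR-106a to miR-363 clusters; the let-7, miR-15/16, miR-29, miR-30, miR-34, miR-181 and miR-23/27/24 families; the family of miR-99, miR-100 and miR-125; miR-221 and miR-222; melanocyte and MITF-linked miRNAs; miR-132/212; markers of epithelial, fibroblast, blood, endothelial, and muscle, neural or liver cells; pluripotency miRNAs; the 14q32 and 19q13 clusters; and endogenous controls. Where 2 rows carry the same printed name, such as miR-126 or miR-9, the table does not say which is the star form. These rows entered only lists that named both, and the 14q32 and 19q13 lists, which took in any arm. Closely related family members can be detected by each other's assays, so values within the let-7, miR-99/100, miR-508/509 and miR-17/106 families are not fully independent. Names are those of the table and follow an older nomenclature.

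The limma test was tested on 20 simulated tables of 165 assays with 30 changed assays each; 1.04% of unchanged assays were called. Changes of 2 log2 units were recovered in 85.5% of cases and changes of 0.5 in 48.5%. Alternatives tried were a fit without the source block, the source as a random block, centring on each sample's median, blanks set to the lowest measured level, assays measured in all 7 or in at least 2 sources, eBayes with a trend and robust prior, an exact sign-flip test per assay, the mean in place of the median, the more abundant assays only, and leaving out each source in turn. Values above a delta Ct of 14 treated as missing, and the 19q13 list without miR-513 and miR-514, were added after the data were seen. The planned settings for raw cycle limits, a pseudocount and endogenous controls did not apply to these values and were not run. Gene neighbourhoods were taken from a RefSeq table of assembly GRCh38.p14, which matched 157 of the 165 tested assays; no coordinates are given because the table of values names no build.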

Results

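Mature microRNAs (miRNAs) were profiled in primary human melanocytes, the pigment-producing cells of the skin, with TaqMan PCR assays. The cells came from 7 independent sources. Each source gave 1 control sample and 1 sample treated with forskolin, a compound that activates adenylyl cyclase and so raises cyclic AMP, the second messenger of melanocortin signalling. The dose and length of the treatment are not given in the sources used here. The panel held 365 miRNA assays, of which 276 gave a value in at least 1 of the 14 samples and 137 gave a value in all 14. Values are cycle differences against the authors' reference (delta Ct), so a lower value means more RNA and 1 cycle corresponds to 1 log2 unit. Changes are given as log2 of forskolin over control, with a positive sign for more RNA after forskolin.

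The most abundant assay in control melanocytes was miR-211, which is encoded in an intron of the melanocyte gene TRPM1 and is driven by the pigment cell factor MITF. Its delta Ct was -1.70 ± 0.26 (SD, n = 7) in control and -1.87 ± 0.27 (SD, n = 7) in forskolin-treated samples. It was followed by miR-146a, a feedback regulator of innate immune signalling, at -0.82 ± 0.18 (SD, n = 7) in control. The next 8 were miR-19b at 2.03, miR-26a at 2.46, miR-125a at 2.97, miR-20a at 3.00, miR-16 at 3.16, miR-24 at 3.29, miR-93 at 3.65 and miR-222 at 4.15. Amplification efficiencies of the assays are not known, so this order ranks delta Ct values rather than molecule numbers.

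The first comparison asked which miRNAs differed between forskolin-treated and control melanocytes of the same source. No miRNA passed the test. Of the 165 assays measured in both samples of at least 4 sources, 0 had an adjusted p below 0.05 in limma's moderated test with the source as a block and Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.181. At an unadjusted p below 0.05 there were 14 assays, 7 higher and 7 lower, against 8.25 expected by chance alone. miR-211 differed by 0.16 ± 0.086 (SE, 7 sources), with a 95% interval from -0.036 to 0.36 and 6 of 7 sources higher. For miR-146a the difference was -0.0043 ± 0.089 (SE), with an interval from -0.21 to 0.21, and it was 0.0014 after each sample was centred on its median. A 2-fold change in either direction was therefore outside the interval for both of these leading miRNAs.

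The 10 assays with the smallest p, none of which passed the adjustment, comprised 6 lower and 4 higher after forskolin. The lower ones were led by miR-508, with a mean delta Ct of 6.17 ± 0.20 (SD, n = 7) in control and 6.52 ± 0.15 (SD, n = 7) after forskolin. Its difference was -0.35 ± 0.073 (SE) and it was lower in 7 of 7 sources (limma adjusted p = 0.181). For miR-99a the difference was -0.68 ± 0.16 (SE), with 7 of 7 sources lower. For miR-509 it was -0.38 ± 0.10 (SE), also with 7 of 7 sources lower. The difference of miR-31, a miRNA linked to cell migration, was -0.60 ± 0.22 (SE) with 7 of 7 sources lower, although in 2 of them the difference was only 0.01 cycles. Values for miR-100 and miR-181c were -0.36 ± 0.12 and -0.64 ± 0.22 (SE), each lower in 6 of 7 sources. The 4 higher assays were all weakly detected. These were miR-324-3p at 1.25 ± 0.32, miR-338 at 0.84 ± 0.21, miR-339 at 0.95 ± 0.26 and miR-34c at 3.01 ± 0.76 (SE), each higher in all but 1 of the sources measured. For miR-34c only 6 sources gave both values, and its mean delta Ct was 18.7 in control and 15.7 after forskolin. With the source as a random block in limma, miR-34c, miR-338 and miR-508 passed at an adjusted p of 0.0236 and miR-324-3p at 0.0468; with a robust prior variance that followed abundance, miR-99a alone passed at 0.0436. Without the only source in which miR-338 was lower, at -0.37, miR-338 passed with a difference of 1.04 and a limma adjusted p of 0.0248. Leaving out any other source gave no call.

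**Figure D1:**
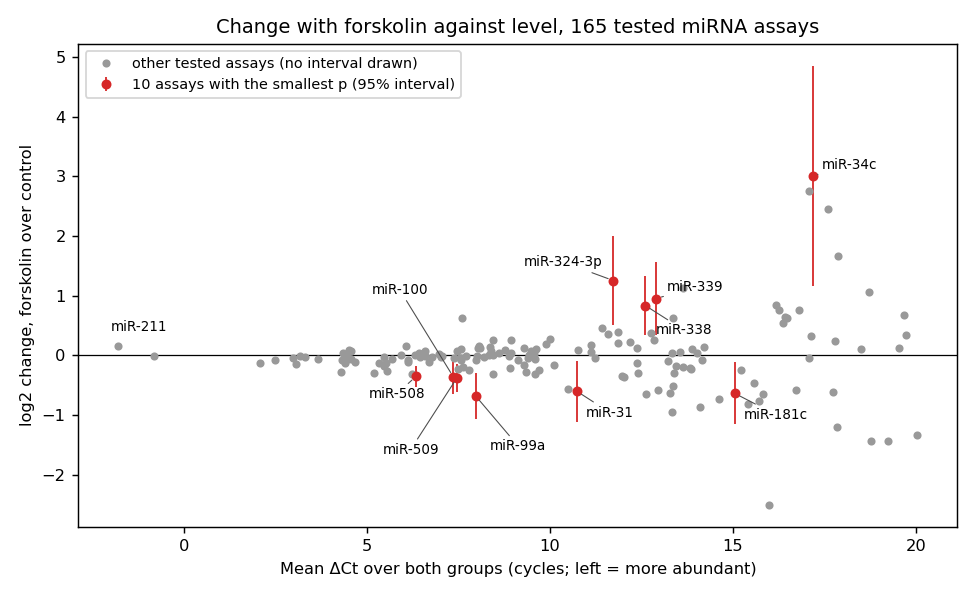
Each point is 1 of the 165 tested miRNA assays. The x axis is the mean delta Ct over both groups in cycles and the y axis is the log2 change of forskolin over control; red points with 95% intervals are the 10 assays with the smallest p. The scatter widens from left to right, and miR-34c, at a change of 3.01, sits among the weakly detected assays.

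**Figure D2:**
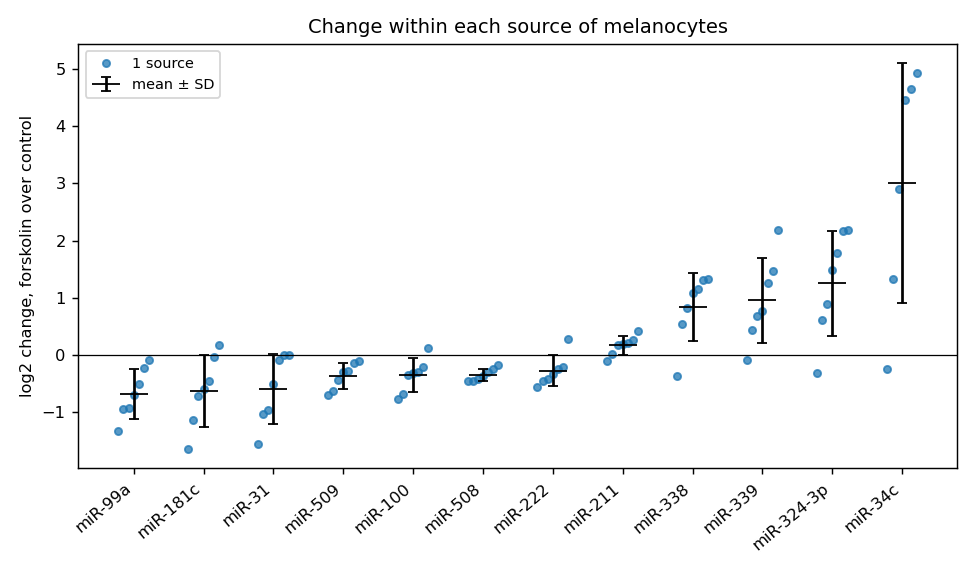
Log2 change of forskolin over control within each of the 7 sources for the 10 assays with the smallest p and for miR-211 and miR-222. Blue points are single sources, and black bars are the mean ± SD; miR-508, miR-509, miR-99a and miR-31 lie below 0 in 7 of 7 sources, while none of the 12 miRNAs shown passed the adjusted threshold.

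The precision of the comparison followed abundance. The SD of the within-source differences had a median of 0.30 for the 91 tested assays with a mean delta Ct below 10, 0.82 for the 38 assays from 10 to 14, and 2.18 for the 36 assays at 14 or more. The 95% interval of the change lay within 1 log2 unit of 0 for 88 of the 91 more abundant assays but for only 16 of the other 74. In data simulated with these levels, sources, blanks and spreads, the test called 96.3% of changes of 1 log2 unit among assays with a mean delta Ct below 10, and 73.0% of changes of 0.5. Over all assays it called 65.5% of changes of 1 log2 unit. Differences of weakly detected miRNAs of that size were often not detectable with these samples. Each simulated table held 30 changed assays among 165, with independent noise. More true changes loosen the adjusted threshold, so these percentages do not give the power to find 1 or a few changed miRNAs.

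The second comparison asked whether the miRNA population as a whole differed. The median log2 change over the tested assays was -0.048 ± 0.12 (SD, n = 7 sources), with 2 of 7 sources above 0 (two-sided exact sign-flip permutation test over sources, p = 0.328). The median delta Ct of the 137 assays measured in every sample was 8.49 ± 0.36 (SD, n = 7) in control and 8.49 ± 0.27 (SD, n = 7) in treated samples. Because the authors had already subtracted a reference from each sample, a change shared by the reference and the miRNAs is not visible in these values. Control samples gave 190 ± 12 detected assays (mean ± SD, n = 7, range 173 to 207) and forskolin-treated samples 182 ± 9.1 (n = 7, range 169 to 192). The within-source difference was -7.86 ± 9.74 assays (SD, n = 7), with 5 of 7 sources lower, and did not pass (two-sided exact sign-flip test, p = 0.0938; the smallest p that 7 sources allow is 0.0156). Without values above a delta Ct of 14 it was -1.86 (exact sign-flip p = 0.125). Detection of single assays could not be tested with effect: among 133 assays with a discordant source, none had more than 5 of them. The smallest p that 5 allow in an exact binomial test is 0.0625, before any adjustment, and the smallest observed was 0.125.

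The third comparison took groups of miRNAs fixed before the data were examined. Of 23 lists, 19 had at least 2 tested members. None of the 19 passed, either in the exact sign-flip test of the mean change per source with Benjamini-Hochberg adjustment or against the other assays with cameraPR at a preset correlation. A single list at the smallest exact p that 7 sources allow, 0.0156, has an adjusted p of 0.297, so the sign-flip test could not call 1 list on its own. In each of the 19 lists, 0 members passed the threshold over all assays. Adjusted over the list alone, 1 member passed in the miR-34 family (miR-34c) and 1 in the family of miR-99, miR-100 and miR-125 (miR-99a), and 0 in the other lists.

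Among lineage miRNAs, the 6 tested members of the melanocyte and MITF-linked list had a mean change of 0.041 ± 0.14 (SD, n = 7 sources; exact sign-flip adjusted p = 0.785). They were miR-211, miR-204 at 0.38 ± 0.58 (SE; 0.053 to 0.87 without 1 source), miR-340 at 0.26 ± 0.14, miR-148a at 0.024 ± 0.12, miR-148b at -0.34 ± 0.20 and miR-101 at -0.24 ± 0.16. Without 1 source, miR-148b ranged from -0.47 to -0.18 and miR-101 from -0.355 to -0.13. miR-137 gave a value in 2 control samples and 1 treated sample, and 1 of the assays printed as miR-182 in 1 control and 2 treated samples; neither was tested, and miR-183 and miR-96 were blank in every sample. miR-132, a miRNA induced by the cyclic AMP response factor CREB, was abundant at a delta Ct of 5.46 in control and 5.49 after forskolin, a difference of -0.027 ± 0.095 (SE) with an interval from -0.25 to 0.20. The pair miR-221 and miR-222, which target the receptor KIT and the cell cycle inhibitor p27, had a mean change of -0.62 ± 1.05 (SD, n = 7; exact sign-flip adjusted p = 0.713), or -0.90 to -0.31 when 1 source was left out. The abundant member, miR-222, was at -0.28 ± 0.11 (SE) with 6 of 7 sources lower, and the weakly detected miR-221 at -0.95 ± 0.64 (SE), or -1.42 to -0.39 without 1 source.

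The 7 tested members of the miR-17~92 cluster, known for promoting proliferation, had a mean change of 0.16 ± 0.45 (SD, n = 7; exact sign-flip adjusted p = 0.785), while their median was -0.12. The mean was carried by miR-17-3p, near the detection limit, at 2.46 ± 1.24 (SE, 5 sources), and without delta Ct values above 14, which left miR-17-3p out, the cluster mean was -0.097. The other members miR-17-5p, miR-19a, miR-19b, miR-20a, miR-18a and miR-92 differed by 0.11 ± 0.15, -0.13 ± 0.11, -0.12 ± 0.10, -0.15 ± 0.14, -0.16 ± 0.19 and -0.12 ± 0.080 (SE), each with an interval inside 1 log2 unit. The related miR-106b~25 cluster had a mean change of 0.027 ± 0.15 (SD, n = 7) and the cluster of miR-106a and miR-363 of 0.40 ± 1.00 (SD, n = 7). The latter rested on 2 tested members, miR-18b at 1.07 (5 sources) and miR-20b at -0.05. Neither miR-106a nor miR-363 was tested. The mean of this cluster was 0.058 to 0.57 when 1 source was left out, 1.21 with blanks at the lowest measured level and -0.65 without the source block. The let-7 family, which restrains growth, had 8 tested members and a mean change of 0.011 ± 0.45 (SD, n = 7; exact sign-flip adjusted p = 0.984), while the median of its members was -0.046 and cameraPR ranked it as lower. For let-7a the difference was 0.0071 ± 0.17 (SE). let-7c was higher in 7 of 7 sources by 0.16 ± 0.073 (SE) and did not pass (limma adjusted p = 0.597). For miR-21 the difference was -0.13 ± 0.15 (SE).

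The 7 members of the family of miR-99, miR-100 and miR-125, which the list groups with miR-10, had a mean change of -0.22 ± 0.19 (SD, n = 7) and were lower in 6 of 7 sources and at 0 in the other (two-sided exact sign-flip p = 0.0312, adjusted p = 0.297). cameraPR gave an adjusted p of 0.197, or 0.596 with an estimated correlation. The difference was -0.31 ± 0.14 (SE) for miR-125b and -0.10 ± 0.17 (SE) for miR-10a. The median member was at -0.10, and miR-99b, miR-125a and miR-10b lay near 0, at 0.0057, -0.043 and -0.060. The 2 tested members of the miR-34 family, known to be induced by p53, had a mean change of 1.33 ± 0.91 (SD, n = 7) and were higher in 7 of 7 sources (exact sign-flip p = 0.0156, adjusted p = 0.297), but miR-34a alone was at -0.29 ± 0.65 (SE), and in 1 source the mean held miR-34a only. The mean changes of the other families were -0.24 ± 0.51 for miR-15/16, -0.086 ± 0.23 for miR-29, -0.025 ± 0.13 for miR-30, -0.21 ± 0.50 for miR-23/27/24 and -0.14 ± 0.58 for miR-181 (SD, n = 7 sources each). The median member was at 0.073 in the miR-181 family and at -0.029 in the miR-15/16 family. The miR-15/16 mean was carried by miR-497, at -2.505 and measured in both samples of only 4 sources. Of 30 assays from the imprinted region at 14q32, 13 gave a value in at least 1 sample, as did 21 of 35 in the list of the primate cluster at 19q13. Each list had 2 tested members, with mean changes of -0.21 ± 0.93 and 0.15 ± 0.71 (SD, n = 7). The number range that defined the 19q13 list also took in miR-514, which lies on chromosome X. The only other tested member of that list was miR-526b.

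Among markers of other cell types, 1 of the assays printed as miR-126, an endothelial miRNA, was well detected at a control delta Ct of 7.52, and the other tested ones lay above 10. miR-203, a keratinocyte miRNA, had a delta Ct of 13.2 in the 5 control samples that gave a value, and miR-200c was at 11.8 in control. Together they had a mean change of -0.38 ± 0.38 (SD, n = 7; exact sign-flip p = 0.0469, adjusted p = 0.297). This mean was -0.93 with blanks set to the lowest measured level and -0.14 without the source block. The fibroblast markers miR-143, miR-145, miR-214 and the measured miR-199a assay had control delta Ct values of 16.6, 15.1, 17.7 and 13.9 and a mean change of 0.68 ± 0.89 (SD, n = 7; exact sign-flip adjusted p = 0.594), which was 0.24 when only assays measured in all 7 sources were used. The blood cell marker miR-223 was measured in 7 control and 4 treated samples; in the 4 sources with both values its change was 1.13 ± 0.35 (SE, limma adjusted p = 0.419), and with the blanks set to the lowest measured level it was -3.69. Both assays printed as miR-126 were measured in every sample and had a mean change of -0.012 ± 0.48 (SD, n = 7). The list of muscle, neural and liver markers had a mean change of 0.017 ± 0.50 (SD, n = 7) over 3 tested assays, miR-133b and the 2 printed as miR-9. The liver marker miR-122a was not tested, so no liver marker entered this mean. None of the 4 pluripotency assays in the list was measured in both samples of 4 sources.

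**Figure D3:**
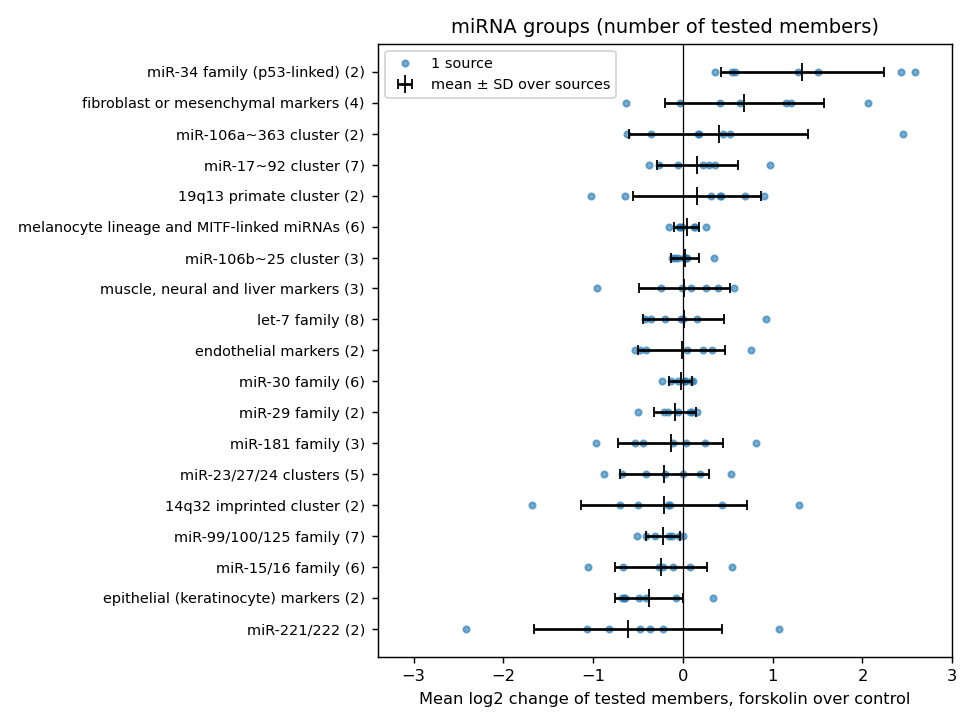
Mean log2 change of the tested members of 19 miRNA groups, forskolin over control, with the number of tested members in parentheses. Blue points are single sources and black bars the mean ± SD over the 7 sources; the widest spreads belong to groups with weakly detected members, such as miR-221 and miR-222 at -0.62 ± 1.05.

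The sources themselves differed far more than the treatments. Over the 137 assays measured in every sample, the source accounted for a median of 81.1% of the sum of squares (quartiles 62.9% and 90.2%), against 46.2% expected from its degrees of freedom alone. The treatment accounted for 1.83% (quartiles 0.281% and 5.96%) with 1 degree of freedom, and the residual for 14.4% with 6. From degrees of freedom alone 7.69% would be expected for the treatment, but only if the sources did not differ. A treatment share below 7.69% therefore does not mark an effect smaller than chance. The 2 assays printed as miR-9, a miRNA best known from neural tissue, spanned 5.97 and 5.35 cycles between the source means, and miR-31 spanned 5.26 cycles. For miR-31 the SD between sources was 2.06 cycles, against an SD of 0.61 for the differences between the samples of a source. These are descriptions without a test.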

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

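No test in this part was chosen after its result was seen. A sample far from the rest of its group was searched for in 254 sets of values, and 20 were found where chance gives about 12.7. In delta Ct, 1 control sample lay above the other 6 for let-7c (9.36, next 8.33, gap 0.592 of the range), for the miR-126 assay 4373269 (12.09, next 11.18, gap 0.717), for miR-181d (8.60, next 7.5, gap 0.786), for miR-23a (17.77, next 14.12, gap 0.596), for miR-508 (6.59, next 6.17, gap 0.70) and for miR-514 (9.40, next 7.77, gap 0.712). Among forskolin samples, 1 lay apart for miR-10a (7.62, next 6.38, gap 0.605), miR-146a (-1.21, next -0.87, gap 0.63), miR-17-3p (22.05, next 16.63, gap 0.677), miR-18a (9.08, next 10.09, gap 0.587) and miR-514 (9.16, next 8.05, gap 0.631). In the change per source, 1 source stood apart for let-7c (0.37, next 0.18, gap 0.594), miR-133b (4.55, next -0.99, gap 0.972, 4 sources), miR-19a (-0.72, next -0.13, gap 0.728), miR-222 (0.27, next -0.21, gap 0.578), miR-23a (2.96, next -0.20, gap 0.751) and miR-379 (4.12, next -0.24, gap 0.769, 5 sources). The same held for the mean change of the miR-106b~25 cluster (0.34, next 0.047, gap 0.64), the cluster of miR-106a and miR-363 (2.45, next 0.53, gap 0.624) and the let-7 family (0.92, next 0.15, gap 0.57).

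Outside the tested assays, miR-624 and the miR-432 assay 4373280 each gave a value in 2 of 7 forskolin samples and in 0 of 7 controls. Their mean delta Ct values were 17.26 and 20.41, and the highest values per sample lay between 21.1 and 22.7. Only assays blank in every control were searched for. Larger cases lay in the opposite direction. miR-325 and miR-367 each gave a value in 4 control and 0 forskolin samples, and miR-383, miR-515-3p and miR-580 each in 3 and 0.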

How the results depend on the processing

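The limit at a delta Ct of 14 and the 19q13 list without miR-513 and miR-514 were chosen after the data were seen. Without miR-514 the 19q13 list had miR-526b as its only tested member, so that list was no longer tested. The calls of the other lists did not change. The absence of a miRNA past the adjusted threshold held (0 calls) without the source block, after centring on sample medians, with blanks set to the lowest measured level, with assays of all 7 or at least 2 sources, and without values above a delta Ct of 14. The exact sign-flip test per assay also gave 0, but its smallest p, 0.0156, could not pass for a few assays among 165, so it says nothing of stability. It did not hold with the source as a random block, which called 4 assays (3 higher, 1 lower), or with a trend and robust prior, which called 1 (lower); leaving out 1 source gave 0 to 1. The source pairs the samples by the labels. Without that replicate block the number at an unadjusted p below 0.05 was 6 instead of 14, and no adjusted call changed. That fit leaves the spread between sources in the error, a median of 81.1% of the sum of squares over 137 assays. Its 0 calls therefore say little of stability. The random block assumes that all assays share 1 within-source correlation; the cause of the added calls was not tested. The overall shift and the difference in detected assays kept their sign and their side of the threshold under every alternative run, with shifts from -0.076 to -0.017 and differences from -10.3 to -6 when leaving out 1 source. Centring takes out a shift of the sample medians by design, so for the overall shift it says nothing of stability. The shift was -0.010 as a mean over assays, and the difference -1.86 (exact sign-flip p = 0.125) without values above a delta Ct of 14. No list passed under any alternative, which says nothing of stability where a single list could not pass the exact test; list means near 0 changed sign. Leaving out 1 source moved the mean by more than 1.5 times in 16 of 19 lists and 53 of 77 named miRNAs; another setting did so in 13 and 15. Without the block, which compares group means over unequal sets of measured members, the miR-17~92 mean was -0.015, the mean of the miR-106a to miR-363 cluster -0.65 and the miR-133b change -0.44. Centring moved miR-146a to 0.0014. With blanks at the lowest level, means were 0.19 for miR-181, -0.64 for muscle, neural and liver markers and 0.32 for 14q32, and changes were -1.90 for miR-133b and -3.69 for miR-223. With all 7 sources required, miR-17~92 was at -0.097 and muscle, neural and liver markers at -0.0071; with at least 2 sources, 19q13 was at -0.23. Without values above a delta Ct of 14, means were -0.097 for miR-17~92, -0.10 for let-7, -0.054 for the melanocyte list, 0.011 for miR-15/16 and -0.23 for muscle, neural and liver markers, and changes were -0.43 for let-7e, -0.19 for miR-204 and -0.080 for the miR-9 assay 4373285; beyond the dropped values the cause was not tested. For lists, further moves by that factor that kept the sign were, after centring, -0.0064 for endothelial markers; without the block, -0.14 for epithelial markers, -0.068 for miR-15/16, -0.44 for miR-181, 0.30 for fibroblast and 0.52 for muscle, neural and liver markers; with blanks at the lowest level, 0.34 for miR-17~92, -0.42 for miR-15/16, -0.93 for epithelial markers and 1.21 for the miR-106a to miR-363 cluster; with all 7 sources, -0.0097 for miR-15/16, -0.28 for miR-181 and 0.24 for fibroblast markers; with at least 2 sources, 0.14 for muscle, neural and liver markers and -0.46 for 14q32; and without values above 14, -0.047 for miR-23/27/24. Of 509 other values of the 77 named miRNAs, 7 changed sign. Leaving out each source in turn changed the sign in 38 of 519 values. The ranges for lists were -0.46 to 0.037 for 14q32, -0.14 to 0.075 for endothelial markers, -0.14 to 0.084 for let-7, -0.026 to 0.051 for miR-106b~25, -0.37 to 0.010 for miR-15/16, -0.37 to 0.0014 for miR-181, -0.048 to 0.010 for miR-30 and -0.19 to 0.23 for muscle, neural and liver markers. Without a change of sign they were 0.029 to 0.35 for 19q13, 0.46 to 0.90 for fibroblast markers, 0.0050 to 0.073 for the melanocyte list, 0.026 to 0.25 for miR-17~92, -0.33 to -0.094 for miR-23/27/24 and -0.13 to -0.016 for miR-29. For single miRNAs they were -0.088 to 0.15 (let-7a), -0.27 to 1.13 (let-7e), -0.032 to 0.060 (miR-106b), -0.087 to 0.0050 (miR-125a), -0.18 to 0.23 and -0.12 to 0.010 (miR-126 assays 4373269 and 4378064), -0.063 to 0.020 (miR-132), -0.80 to 0.033 (miR-145), -0.043 to 0.037 (miR-146a), -0.068 to 0.082 (miR-148a), -0.078 to 0.023 (miR-15b), -0.047 to 0.023 (miR-16), -0.013 to 0.14 (miR-181d), -0.013 to 0.20 (miR-199a), -0.13 to 0.038 (miR-20b), -0.072 to 0.027 (miR-24), -0.055 to 0.12 (miR-27a), -0.11 to 0.013 (miR-29a), -0.080 to 0.047 (miR-30e-3p), -0.77 to 0.060 (miR-34a), -0.88 to 0.54 (miR-379), -0.52 to 0.22 (miR-424), -0.080 to 0.47 and -0.45 to 0.050 (miR-9 assays 4373285 and 4378074) and -0.13 to 0.033 (miR-93). The intervals of 61 of 165 assays reached beyond 1 log2 unit; 88 of the 91 assays with a mean delta Ct below 10 stayed inside it, against 16 of the other 74.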

Other observations

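The tests on reference shifts, on cross-detection, on the miR-506 to miR-514 group, on let-7c, on scatter, on neighbours, on arms and on the number of adjusted calls were chosen after the results they concern were seen. Melanocytes of all 7 sources expressed a group of miRNAs that the RefSeq table lists together on chromosome X (miR-514 there under a later name). Besides miR-508 and miR-509, these were miR-514, at a delta Ct of 7.67 in control and 7.91 after forskolin, and miR-506, at 10.2 and 10.8. The difference was -0.24 ± 0.14 (SE) for miR-514 and -0.56 ± 0.36 (SE) for miR-506, neither past the threshold (limma adjusted p = 0.697 for each). Both arms of miR-324 were higher after forskolin in 6 of 7 sources, with miR-324-5p at 7.90 in control and 7.28 after forskolin, a change of 0.63 ± 0.24 (SE, limma adjusted p = 0.435). miR-506 and miR-324-5p are named here after their values were seen.

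Whether the forskolin labels matter at all was tested by exchanging the labels within whole pairs, which makes 64 ways. The real labels gave 0 adjusted calls, so all 64 ways gave at least as many by construction (highest other value 1), and this count says nothing about chance. At an unadjusted p below 0.05 the real labels gave 14 assays, and 4 of the 64 ways gave as many, with a highest other value of 25. Chance is not excluded for that count. Of 100 random splits of the 14 samples that did not have to part the pairs (the real one included), 9 gave 14 or more, with a highest other value of 19; such splits keep some pairs whole and so estimate the change from fewer sources.

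miR-508 and miR-509 were lower in 7 of 7 sources. A shift of the authors' reference relative to most miRNAs is argued against. After each sample was centred on its median, the mean change of miR-508 and miR-509 was -0.36 ± 0.054 (SE). A shift that the reference shared with most miRNAs is not visible in these values and stays open. Chance among 165 assays stays open: 20 of the 64 ways of exchanging labels gave an assay with as small a p. A candidate explanation is a joint change of this chromosome X group, for which the mean of miR-506 and miR-514 was -0.40 ± 0.23 (SE), lower in 6 of 7 sources but not past the test (exact sign-flip p = 0.0781). Detection of related family members by each other's assays was not tested, nor was a direct effect of cyclic AMP.

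miR-99a and miR-100 differ little in sequence and were both lower. A reference shift relative to most miRNAs is argued against by a mean change of -0.52 ± 0.11 (SE) after centring. An equal fall of every miRNA made from the miR-99a host transcript is argued against by let-7c, next to miR-99a, whose interval started at -0.011 while miR-99a was at -0.68. This rests on let-7c alone, since other miRNAs of that transcript were not examined for it. In addition, let-7 assays can detect related family members. Cross-detection between the miR-99a and miR-100 assays could give joint changes: Pearson's r of their changes over 7 sources was 0.75 (exact permutation p = 0.0494) and Spearman's rho 0.57 (p = 0.20). Without the 2 sources farthest from the median, r was 0.36. Dropping them also narrows the range of the changes, so this fall does not show that the relation rests on them. Cross-detection stays open. This was the only pair for which a correlation was computed.

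Among weakly detected assays, miR-324-3p, miR-338, miR-339 and miR-34c were higher. Of the 74 tested assays with a mean delta Ct of 10 or more, 51.4% had a positive change (38 assays, exact binomial p = 0.908), a balance that does not speak to 4 assays picked for their p. Scatter of weakly detected assays stays open, with a median SD of within-source differences of 0.82 for assays from 10 to 14. However, 3 of the 4 were measured in all 14 samples, with group means from 11.1 to 13.4. These means lay below the highest values per sample, 21.1 to 22.7. A reference shift relative to most miRNAs is argued against by a mean change of the 4 of 1.44 ± 0.32 (SE) after centring. A response of these miRNAs to forskolin was not excluded.

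A broader hypothesis, that miRNAs within 10 kb of each other change together, found no support: over 64 neighbouring pairs the mean product of normal scores was -0.046 (one-sided permutation of assay labels, 10000 permutations, p = 0.619). For the 6 pairs of assays from 1 precursor the same measure was 0.67 (permutation p = 0.0376), but it was 0.028 (p = 0.462) over the 5 pairs without miR-324, whose values had been seen, so joint change of arms stays open. The largest pairs were miR-324 (1.25 and 0.63) and miR-17 (2.46 and 0.11), and in 3 of the 6 pairs the arms had opposite signs. Genes are not independent replicates, and with 2 such tests the adjusted p of the arms is 0.0752.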
